A study of Rattus norvegicus with 12 samples.

How the data were processed

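RNA from cultured rat pituitary cells was measured on 12 Affymetrix Rat Expression Array 230 2.0 oligonucleotide arrays, 1 array per sample. The agent given to each sample was taken from its label, and so was its enrichment set. An enrichment set is a separate preparation of gonadotrope-enriched cells, and the labels describe 3 of them. Each set holds 2 vehicle and 2 GnRH samples. Total RNA was extracted on silica columns with DNase digestion and amplified in a pair of rounds with T7 RNA polymerase, per the labels' protocols. Such amplification shortens the product toward the 3' end of each transcript. The deposited values are probe set intensity signals on a linear scale, computed with GCOS (GeneChip Operating System), per the series' design text and the submitters' processing notes; its version and settings are not given in the sources used here. Their trimmed means lay between 497 and 499 on all 12 arrays, so the authors' values had been scaled to a common target before they were deposited. The labels state that the scanner files of set I were lost, and no scanner file was used here. No per-sample column other than those of the 12 samples was in the table.

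The table holds 31099 probe sets, of which 57 are array controls and 31042 are not. In the platform annotation, 20826 probe sets carry 1 gene symbol, 436 carry several and 9780 carry none. Of the probe sets with 1 symbol, 20764 had an Entrez identifier in the RefSeq gene table of assembly GRCr8, and 0 symbols changed through it. No gene was named from a probe set with several symbols, and no coordinates were used because the probe sets were not aligned to a genome here. Each array was rescaled to a trimmed mean of 500 over its non-control probe sets, with 2% trimmed at each end. After addition of a pseudocount of 16, values were taken to the log2 scale. A fold change given here is therefore on the scale of signal plus 16 and understates the change of dim genes. Probe sets were tested when their mean log2 value lay at or above the 40th percentile of non-control probe sets. This left 18625 probe sets, 13655 of them with 1 gene symbol, and 10680 genes.

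GnRH and vehicle samples were compared in limma 3.58.1 under R 4.3.3. The linear model held the enrichment set and the agent, variances were moderated with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Moderated F tests compared the enrichment sets and tested whether the GnRH response differed between them. The same test was also run within each set of 4 arrays. The study's own criterion, a fold of at least 1.50 with concordance in at least 50% of pairwise comparisons, was applied on the same log2 scale, after addition of the pseudocount. A probe set counted as up when the ratio of the groups' geometric means of signal plus 16 was at least 1.50 and at least 50% of the 36 GnRH-vehicle pairs reached 1.50. The rule was mirrored for probe sets down. GCOS change calls, which the study used for concordance, were not recomputed.

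Gene lists were fixed before the data were examined, as were the tests, the main settings and the rule for named genes. The 26 lists covered immediate early transcription factors, other immediate early genes, MAPK and G-protein feedback regulators, cAMP and CREB target genes, gonadotropin and receptor genes, Rap and Ras GTPases and their regulators, GnRH receptor signalling components, unfolded protein response genes, NF-kB and inflammatory genes, heat shock and dissociation stress genes, secretory granule and exocytosis genes, steroid hormone receptors and coregulators, cytoskeleton and adhesion genes, TGF-beta and activin pathway genes, housekeeping genes, cytosolic ribosomal protein genes and oxidative phosphorylation genes. The rest were markers of gonadotropes, somatotropes and lactotropes, corticotropes and melanotropes, thyrotropes, folliculostellate and stem cells, endothelial cells, fibroblasts and pericytes, leukocytes, and erythrocytes. Each gene was represented by its tested probe set with the highest mean signal. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of lists were taken over the 25 lists with tested members. The mean log2 value of a list per sample was compared by an exact two-sided permutation test within enrichment sets, whose smallest possible p is 0.00926.

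Genes named in the text are Rap1b, a set of pituitary hormone and immediate early genes written down beforehand, every gene with an adjusted p under 0.05 and the same sign in all 3 sets, and up to 3 members with the smallest p from each list. For the tests on enrichment sets, the 6 genes with the smallest p were taken. Some genes of the lists are not reported here.

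The labels title the samples as biological replicates in numbered order, and nothing says that wells of 1 preparation came from separate cultures. The p-values therefore measure the spread between these samples, part of which may be technical. Replicate numbers were checked for pairing across the agents by correlating deviations from the means of each agent and set, and beyond the set itself they did not pair samples. The number of arrays limits the precision. The median standard error of a GnRH minus vehicle difference was 0.48 on the log2 scale.

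The GnRH comparison, the interaction test, the list test, the permutation test and the fold rule were tested on simulated data; the F test between enrichment sets was not. Values for the GnRH comparison were drawn for the same 18625 probe sets with their own means and residual spread, once with equal noise on all arrays and once with array-specific noise as estimated. With array-specific noise, 43.5% of 200 probe sets changed by 2 on the log2 scale were called, 79% of those changed by 3, and 0% of those changed by 1. With no change simulated, 0 probe sets were called under array-specific noise and 1 under equal noise. The list test and the fold rule were simulated with equal noise only. The list test gave 1 call in 20 data sets with no change and called a list shifted by 0.5 in 20 of 20. Genes were drawn independently of each other there. The simulation therefore cannot show how the preset correlation performs where genes of a list vary together.

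Alternatives covered the pseudocount, the filter, quantile normalization, values as deposited, the set as a fixed or random term or left out, the replicate number as a block, each set alone or left out, array weights, variance moderation without trend or with robust settings, 1 probe set per gene, and each array left out in turn. Alternatives added after the data were seen used only the 5 arrays with the lowest spike-in signal without a set term, took the spike-in level as a covariate, or removed shared genes from the cAMP list. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.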

Results

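Gene expression was measured in gonadotrope-enriched cultures of the rat anterior pituitary. Gonadotropes are the pituitary cells that make luteinizing hormone (LH) and follicle-stimulating hormone (FSH), and gonadotropin-releasing hormone (GnRH) is the hypothalamic peptide that controls them. Pituitaries came from adult female Sprague-Dawley rats 2 weeks after ovariectomy, 13 to 15 per experiment. Large cells, about 6% of those recovered, were collected after sedimentation at unit gravity. According to the labels, 40 to 60% of the collected cells stained for LH, against fewer than 7% before separation. On culture day 3 the cells received 10 nM GnRH or vehicle for 40 min. The 12 arrays comprised 6 vehicle and 6 GnRH samples from 3 preparations, enrichment sets I, II and III, with 2 samples of each agent per set.

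The arrays differed in how strongly the sample RNA was detected relative to bacterial hybridisation controls, which are spiked in at fixed amounts. After scaling, the geometric mean spike-in signal was 7634 and 7952 in vehicle 1 and 2, 7853 and 11705 in GnRH 1 and 2, and 2264 in vehicle 5. It was far higher on the other 7 arrays, from 53482 in vehicle 6 to 320024 in vehicle 3. Set I therefore held only arrays with low spike-in signal, set II only arrays with high signal, and set III both kinds. The mean log2 spike-in level was higher in GnRH than in vehicle samples by 0.96, which did not exceed the spread (exact within-set permutation p = 0.5, two-sided, n = 6 per group). Vehicle 3 stood apart, with a median Spearman correlation of 0.34 with the other arrays, against 0.62 to 0.69 for the rest. These medians do not show that the rest formed groups by spike-in level. Arrays with low spike-in signal correlated at 0.875 to 0.952 with each other. Those with high signal, vehicle 3 aside, correlated at only 0.618 to 0.727 with each other. The 3' to 5' signal ratio, a sign of RNA integrity and product length, did not differ detectably between agents. Its GnRH minus vehicle log2 difference was -0.18 for Gapdh (exact within-set permutation p = 0.528) and 0.47 for Actb (exact p = 0.185).

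**Figure D1:**
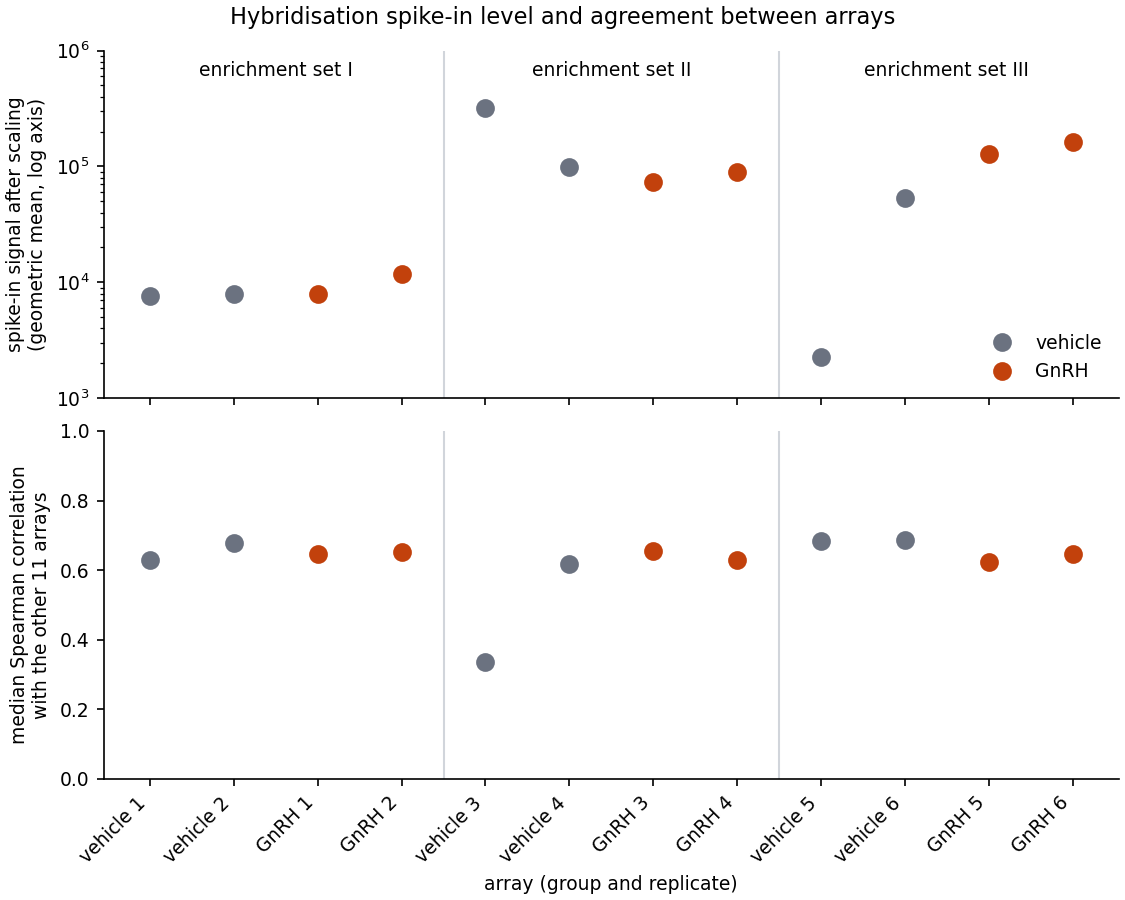
Geometric mean signal of the hybridisation spike-ins after scaling (log axis, above) and median Spearman correlation of each array with the other arrays (below), for vehicle and GnRH samples ordered by enrichment set, 1 point per array. Spike-in signals ran from 2264 to 320024, and vehicle 3 had the lowest median correlation, 0.34.

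The main comparison asked which transcripts differed after 40 min of GnRH. Fosb, which encodes a FOS-family subunit of the AP-1 transcription factor, rose 4.90-fold (95% confidence interval 3.05 to 7.87). Its log2 difference was 2.29 ± 0.32 (SE, n = 6 per group; limma adjusted p = 0.0411), and the differences within sets I, II and III were 2.03, 3.01 and 1.84. Arc, which encodes an activity-regulated cytoskeletal protein best known from neurons, was 5.97-fold higher in GnRH samples (interval 3.08 to 11.6). Its log2 difference of 2.58 ± 0.45 (SE) missed the threshold over all probe sets (limma adjusted p = 0.277) and passed it adjusted over the list alone (limma adjusted p = 0.000861). The Arc signal of vehicle 3, 4 and 6 (116, 94.8 and 65.6) lay near the mean of background bacterial controls on the 7 arrays with high spike-in signal. That mean was 6.47 as log2 signal without the pseudocount, so the size of the Arc fold is uncertain. Each GnRH sample exceeded each vehicle sample in the signal of Fosb and of Arc, in 36 of 36 pairs, and for Arc 100% of pairs differed by at least 1.50-fold.

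Fosb was the 1 probe set of 18625 that passed the limma threshold over all probe sets, and 0 passed as lower. At an unadjusted p under 0.05 there were 643, of which 349 were higher and 294 lower in GnRH samples, against 931 that chance alone would give. Among the tested members of the fixed lists, the 4 smallest p-values belonged to Fosb, Arc, Errfi1 and Nr4a3. The call of Fosb was lost when any array other than vehicle 3 was left out, with limma adjusted p from 0.00358 to 0.310 over the 12 omissions while the log2 difference stayed between 2.01 and 2.43. Within sets I, II and III alone, 0 probe sets passed by limma, with 690, 808 and 494 at an unadjusted p under 0.05.

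**Figure D2:**
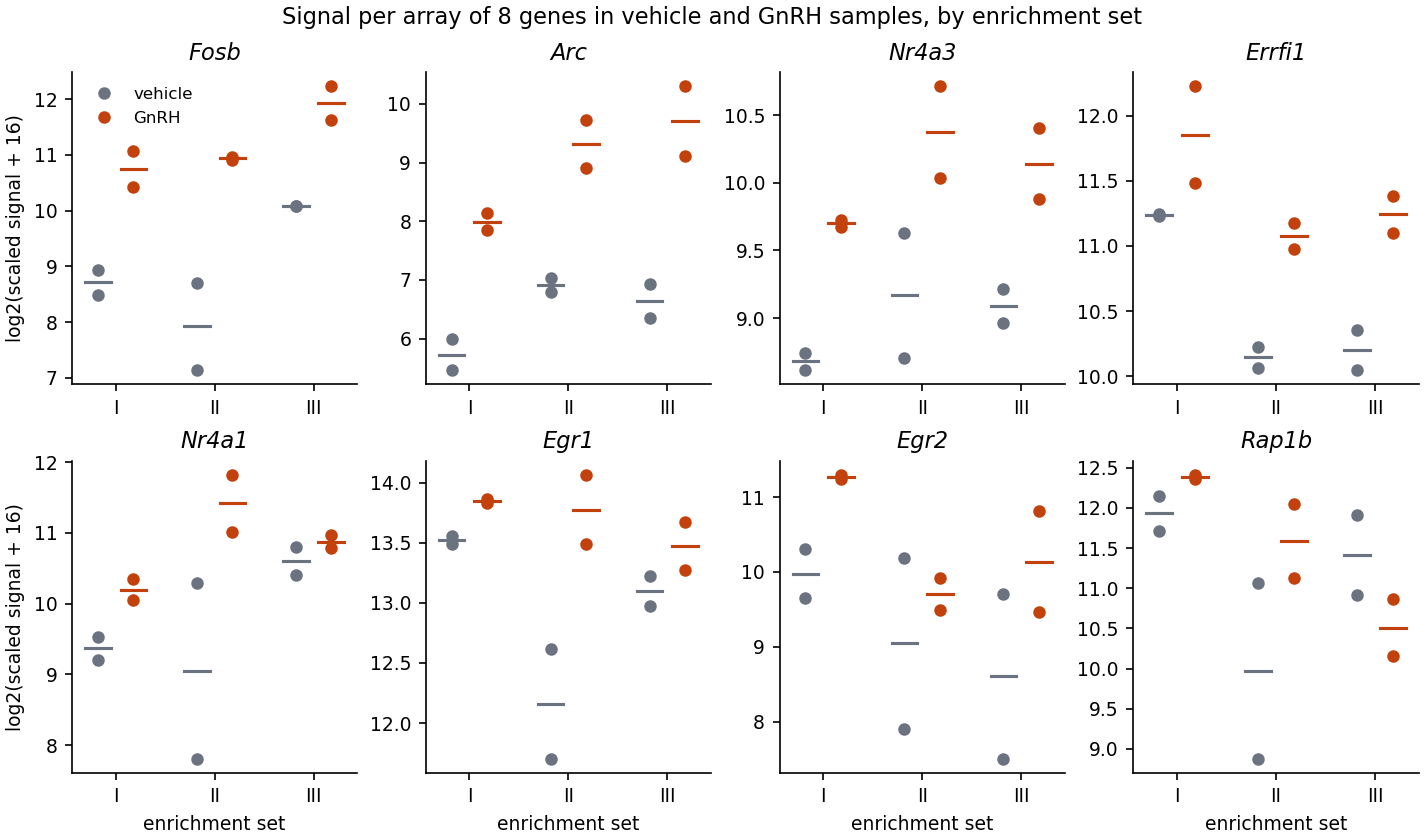
Signal of 8 genes as log2(scaled signal + 16) per array, by enrichment set (horizontal axis), with a point per array and a bar at the mean of each agent within a set. Fosb, Arc and Nr4a3 were higher in both GnRH samples than in both vehicle samples of each set, whereas the mean of Rap1b was higher in GnRH samples in sets I and II and lower in set III.

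The immediate early transcription factors, genes induced within minutes of a stimulus without new protein synthesis, were higher in GnRH samples as a group. Of 32 tested members, 22 were higher, and the mean log2 difference was 0.43, with 0.35, 0.66 and 0.26 in sets I, II and III. By limma's camera the list rose (adjusted p = 0.000603 over 25 lists); adjusted p = 0.136 with an estimated correlation. The mean over the list also differed by the exact within-set permutation test (p = 0.00926, the smallest it can give, and 0.116 after adjustment over the lists). Over all probe sets 1 member, Fosb, rose, and adjusted over the list alone 2 rose, Fosb and Nr4a3, with 0 down. Nr4a3, an orphan nuclear receptor, was 2.14-fold higher (log2 1.09 ± 0.29 SE; limma adjusted p = 0.0261 over the list alone), with similar differences of 1.02, 1.21 and 1.06 in the 3 sets. Its other tested probe sets gave 1.47 and 0.91, and the latter was higher in sets I and II (1.30 and 2.42) and lower in set III.

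Other members were higher by values that did not pass the adjusted test. Egr2 and Egr1, zinc-finger factors that respond to MAPK signalling, differed by 1.16 ± 0.44 and 0.77 ± 0.29 on the log2 scale (SE), and EGR1 is a known activator of the Lhb promoter. The nuclear receptor gene Nr4a1 differed by 1.16 ± 0.41, and by 0.70 to 1.32 with each array left out. Among AP-1 subunits, Junb differed by 0.81, Jun by 0.73 and Fos by 0.42. The Fos difference was 0.63 and 1.74 in sets I and II and -1.09 in set III. The set III value rests on vehicle 5, the array of that set with low spike-in signal. Its Fos signal was 4565, against 586 in vehicle 6 and 387 and 1492 in GnRH 5 and 6. With each array left out, the Fos difference ran from 0.14 to 0.98. Jun differed by -0.08, 2.19 and 0.07 in sets I, II and III and by 0.32 without vehicle 3, and Junb by 0.42 without vehicle 4. The other tested probe sets of Jun gave 0.12 and 0.13. Atf3 differed by 0.51 and Klf4 by 0.05, each less than the spread. In all, 13 of the 32 members (40.6%) were higher in each of the 3 sets, against 12.3% of all 10680 genes tested. In lists without a call this share ran from 0% for leukocyte markers to 50% of the 4 gonadotropin and receptor genes. It was 30% for housekeeping genes, so exceeding the share of all genes is not particular to the immediate early factors.

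**Figure D3:**
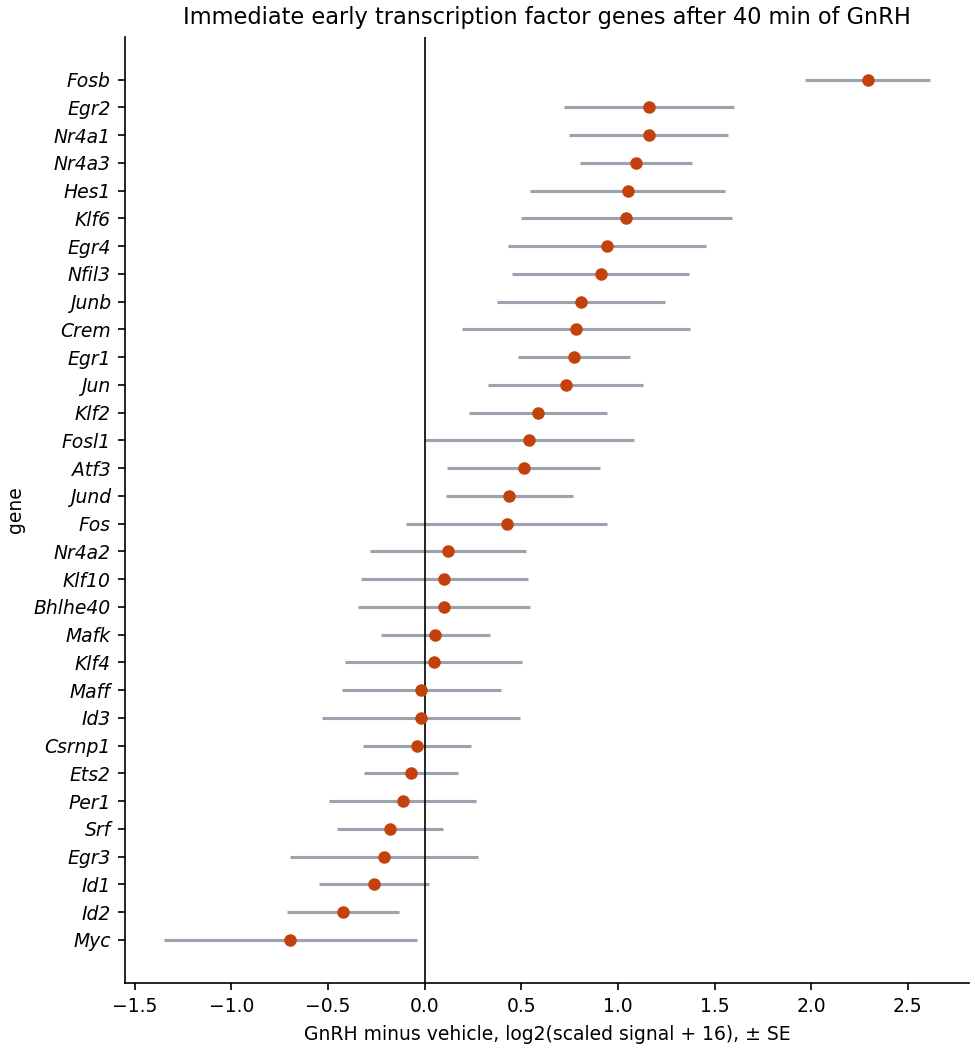
GnRH minus vehicle difference of the 32 tested immediate early transcription factor genes, in log2(scaled signal + 16), with standard errors from limma (12 arrays). Fosb lies at 2.29, and 22 of the 32 genes lie above 0.

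MAPK and G-protein feedback regulators, which are induced by signalling and damp it, also rose as a list. The mean log2 difference of the 18 tested genes was 0.39, and 16 were higher in GnRH samples (limma's camera adjusted p = 0.00336). That call was lost with adjusted p = 0.268 with an estimated correlation. Errfi1, a feedback inhibitor of the epidermal growth factor receptor, was 1.82-fold higher (log2 0.86 ± 0.23 SE; sets 0.61, 0.93 and 1.04). Adjusted over the list alone it was the 1 member that rose (limma adjusted p = 0.0294), and 0 rose over all probe sets. Rgs4 and Rgs2, regulators of G-protein signalling, differed by 0.65 and 0.34, the pseudokinase gene Trib2 by 0.62 and the MAPK phosphatase gene Dusp1 by 0.49. A further tested probe set of Trib2 gave -0.58. Leaving out each array in turn gave 0.33 to 0.85 for Rgs4, 0.11 to 0.51 for Rgs2, 0.35 to 0.86 for Trib2 and 0.36 to 0.73 for Dusp1. Over all alternatives, each set alone included, their lowest values were 0.16, -0.49, -0.70 and -0.28.

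The other immediate early genes and the cAMP and CREB target genes rose as lists by limma's camera (adjusted p = 0.0227 and 0.00336). With an estimated correlation their adjusted p-values were 0.429 and 0.268. Among 29 other immediate early genes, 21 were higher, with a mean log2 difference of 0.33, and adjusted over the list alone Arc rose. Its call as a list ended without vehicle 1, vehicle 3, GnRH 1 or GnRH 4, with adjusted p up to 0.111. Ifrd1 and Ier2 differed by 0.78 and 0.32, whereas the kinase gene Plk2 was lower (log2 -1.20 ± 0.41 SE). Plk2 did not pass over the list alone (limma adjusted p = 0.145), and its set I difference was -0.02. Among 16 tested cAMP and CREB targets, 11 were higher, with a mean of 0.43, and adjusted over the list alone Fosb and Nr4a3 rose. These genes also belong to the immediate early list. Without genes shared with the immediate early lists, an analysis added after the data were seen, 8 cAMP targets remained and limma's camera gave an adjusted p of 0.785.

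The spike-in level of the arrays moved with the enrichment set, so these lists were also tested on the 5 arrays with the lowest spike-in signal, an alternative chosen after the data were seen. These are the 4 arrays of set I and vehicle 5, which has no GnRH mate among them, and with no set term in that model a difference between preparations is mixed with that between agents. There the immediate early transcription factors and the MAPK feedback regulators were called, and 2 lists in all. The other immediate early genes (limma's camera adjusted p = 0.0571) and the cAMP targets (0.351) were not. In set I alone all 4 lists were called, and in set II or set III alone 0 were.

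**Figure D4:**
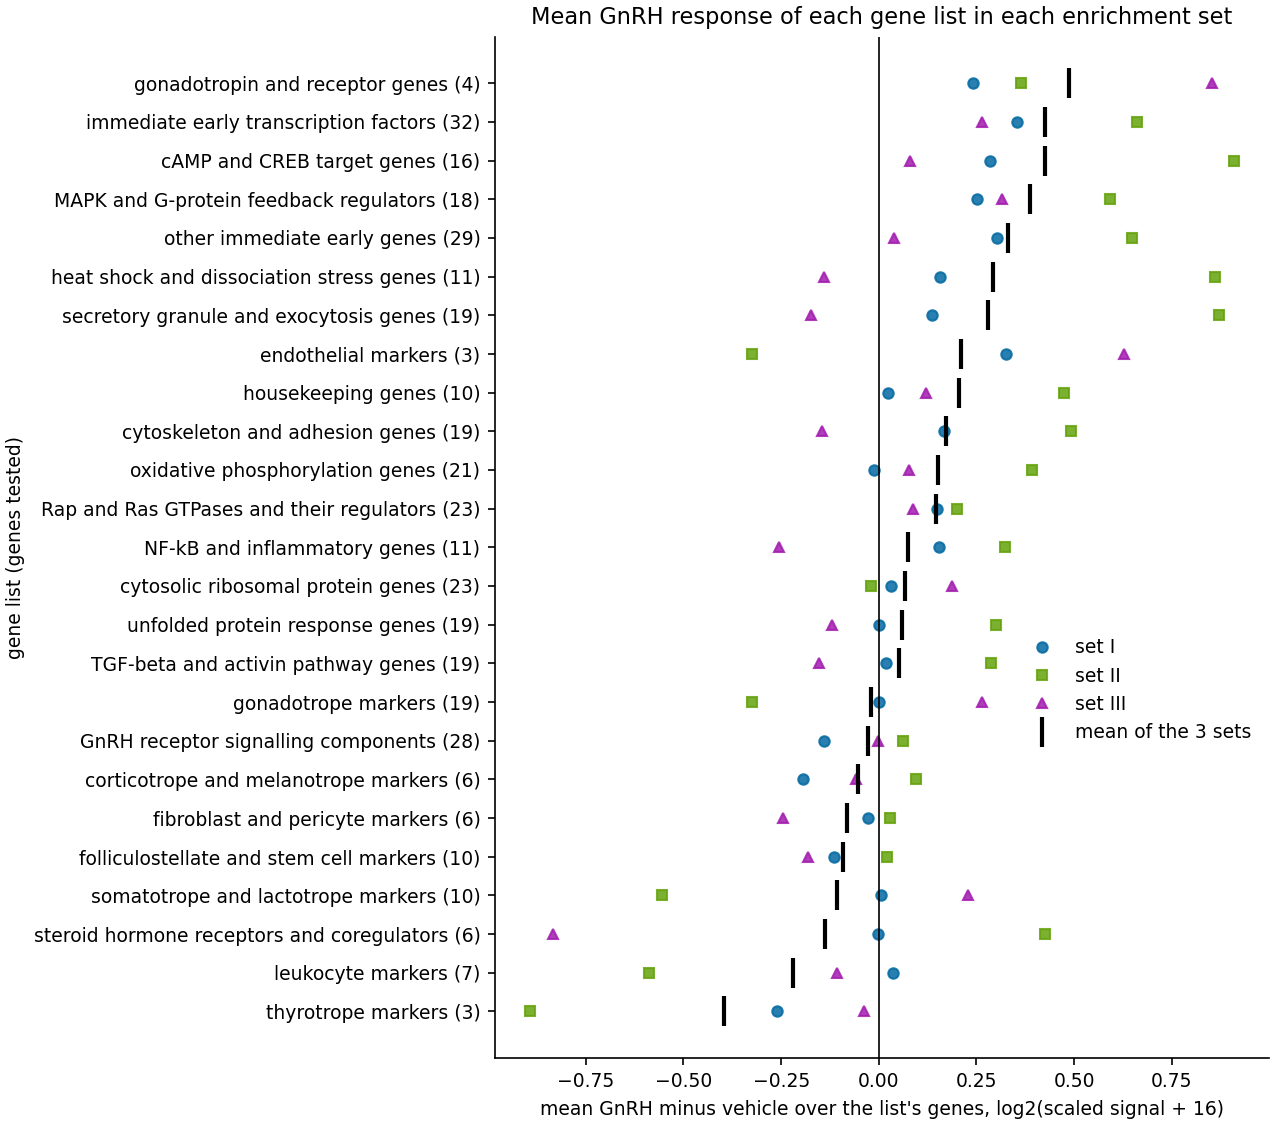
Mean GnRH minus vehicle difference over the tested genes of each list, in log2(scaled signal + 16), within each enrichment set (symbols) and averaged over the 3 sets (black bars). The immediate early transcription factors lie at 0.35, 0.66 and 0.26 in sets I, II and III.

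The gonadotropin and receptor genes, the products that define the target cell, were higher in 4 of 4 cases without passing the test. Cga, the subunit shared by LH, FSH and thyroid-stimulating hormone, differed by 0.89 ± 0.67 (log2, SE), Lhb by 0.74 ± 0.55, Gnrhr by 0.18 ± 0.53 and Fshb by 0.13 ± 0.29. The differences in sets I, II and III were 0.13, 0.15 and 2.40 for Cga and 0.13, 0.46 and 1.63 for Lhb. Without vehicle 5, the array of set III with low spike-in signal, the differences over all sets were 0.23 for Cga and 0.18 for Lhb. A further tested probe set of Gnrhr gave 0.75. The list's mean was 0.49 (limma's camera adjusted p = 0.337). The signals of Lhb and Cga moved with the spike-in level, being 4.97-fold and 6.77-fold brighter on the 7 arrays with high spike-in signal than on the other 5. The Gnrhr signal of vehicle 3, 4 and 6 (90.1, 70.4 and 74.5) lay near or below the background controls' mean on the 7 arrays. So did that of GnRH 3 and 5 (71.4 and 40.3), which leaves the size of the Gnrhr difference uncertain. The wider gonadotrope markers had a mean of -0.02 and a median of 0.13 over 19 genes (adjusted p = 0.723 for a lower list), where Scg2, a granin of secretory granules, was higher by 0.68. The transcription factor genes Foxl2 and Nr5a1 differed by -0.67 and -1.15, though the Nr5a1 signal of GnRH 4 (26.2) lay below the background controls' mean on such arrays. None of these passed adjusted over the list alone.

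Markers of other pituitary and supporting cells showed no list call by limma's camera. Pomc, the precursor of adrenocorticotropin made by corticotropes and melanotropes, was lower in GnRH samples (log2 -1.77 ± 0.50 SE). Its signal in GnRH 3 to 6 (34.1 to 81.4) lay below the background controls' mean on such arrays (6.47 as log2 signal without the pseudocount). The size of that difference is therefore uncertain. Pomc fell adjusted over the list alone (limma adjusted p = 0.0166) and missed the threshold over all probe sets (adjusted p = 0.981). Its differences were -0.55, -2.35 and -2.40 in sets I, II and III, and -0.02 on the 5 arrays with the lowest spike-in signal, where vehicle 5 of set III was pooled with set I without a set term. The other leading members of that list, Tbx19 and Pcsk2, were higher by 0.64 and 0.56. With each array left out they ran from 0.26 to 0.85 and from 0.10 to 0.87. The list as a whole had a mean of -0.05 and a median of 0.38 (limma's camera adjusted p = 0.866). Somatotrope and lactotrope markers had a mean of -0.11 (adjusted p = 0.615), with Gh1 at 0.67 (-0.11 without vehicle 5), Prl at 0.37, Rxrg at -0.67 and Agtr1b at -1.05. The other tested probe set of Rxrg gave 0.45. The Agtr1b signal of GnRH 5 and 6 (12.9 and 22) lay below the background controls' mean, so the size of its difference is uncertain. Gh1 and Prl were 11.9-fold and 2.87-fold brighter on the 7 arrays with high spike-in signal. Thyrotrope markers (Tshb 0.21, Dio2 -0.64, Trhr -0.76) had a mean of -0.40 (adjusted p = 0.511). The Trhr signal of GnRH 3 (22.4) lay below the background controls' mean. So did the Dio2 signal of GnRH 3 and 6 (36.5 and 29.4) and of vehicle 4 (55.3).

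Folliculostellate and stem cell markers (Anxa1 0.62, Gfap 0.84, Aldh1a2 -0.80) had a list mean of -0.09 (limma's camera adjusted p = 0.878). Endothelial markers (Esam 0.43, Tek 0.24, Kdr -0.04) had a mean of 0.21 (adjusted p = 0.690). Fibroblast and pericyte markers (Acta2 -0.52, Dcn -0.48, Col1a1 0.27) had a mean of -0.08 (adjusted p = 0.615), and the other tested probe set of Col1a1 gave -0.41. Leukocyte markers (C1qa -0.99, Fcer1g -0.49, Cd74 0.51) had a mean of -0.22 (adjusted p = 0.337). The C1qa signal lay near or below the background controls' mean in vehicle 3 (88.3) and GnRH 3, 5 and 6 (83.3, 51.2 and 58.4). None of the 6 erythrocyte markers listed was tested. In each of these lists 0 members passed adjusted over the list alone.

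Rap1b, the small GTPase named in the study's title, was 1.31-fold higher in GnRH samples, with an interval from 0.704 to 2.44. The log2 difference was 0.39 ± 0.42 (SE, n = 6 per group; limma adjusted p = 0.981), less than the spread between samples. It was 0.46 in set I, 1.62 in set II and -0.91 in set III. With each array left out it ran from -0.04, without vehicle 3, to 0.68. In set III the Rap1b signal was 3835 in vehicle 5, the array with low spike-in signal, and 1917 in vehicle 6. In GnRH 5 and 6 it was 1122 and 1843. Of the 36 GnRH-vehicle pairs, 38.9% reached 1.50-fold. Because the study singled Rap1b out on samples of this kind, its direction here is not independent evidence. The Rap and Ras GTPases and their regulators had a mean of 0.15 over 23 genes (limma's camera adjusted p = 0.337), of which 0 passed adjusted over the list alone. The members with the smallest p were Cdc42, Rac1 and Rap1a. Cdc42 differed by 0.44 to 0.76 and Rac1 by 0.41 to 0.98 with each array left out. Rap1a, a close relative of Rap1b, differed by 1.09 ± 0.56 (log2, SE), and its other tested probe set gave 0.07. Over all alternatives, each set alone included, Rap1a ran from -0.73 to 3.53. Its signal in vehicle 3 and 4 (78.6 and 92.6) lay near the background controls' mean on such arrays.

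Stress and secretion genes came closest among the 21 lists without a call. Secretory granule and exocytosis genes had 17 of 19 members higher and a mean of 0.28 (limma's camera adjusted p = 0.0778), led by Scg2, the processing enzyme gene Cpe (0.68) and Syt4 (0.55). Heat shock and dissociation stress genes had 10 of 11 higher and a mean of 0.29 (adjusted p = 0.0815), with Hmox1 at 1.02 (0.26 without vehicle 3), Hsph1 at 0.34 and Dnaja1 at 0.32. Other probe sets of Hsph1 and Dnaja1 gave 0.17 and 0.56. With an estimated correlation both lists had an adjusted p of 0.703. The means in sets I, II and III were 0.14, 0.87 and -0.17 for secretory genes and 0.16, 0.86 and -0.14 for heat shock genes. Vehicle 3 of set II had a lower secretory list mean (9.90) than the other vehicle arrays (10.89 to 11.23). It was also lower in the heat shock list mean (9.93 against 11.08 to 11.55). Whether the response of these lists differed between sets was not tested.

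The remaining lists did not pass by limma's camera and had 0 members past the threshold adjusted over the list alone. GnRH receptor signalling components had a mean of -0.03 (adjusted p = 0.615), with the inositol trisphosphate receptor gene Itpr3 at -1.42, Plcb2 at 1.11 and the calmodulin gene Calm2 at 0.55. The Itpr3 signal of GnRH 4 (46) lay below the background controls' mean on arrays with high spike-in signal. So did the Plcb2 signal of vehicle 4 (50.8). Unfolded protein response genes had a mean of 0.06 (adjusted p = 0.716; Creld2 0.55, Canx 0.59, Chac1 0.45), and the other tested probe set of Canx gave -0.31. Canx ran from 0.17 to 0.80 and Chac1 from 0.20 to 0.57 with each array left out. NF-kB and inflammatory genes had a mean of 0.07 (adjusted p = 0.797), with Bcl3 at 1.11 (0.26 for its other probe set), Nfkbiz at -0.92 and Tnfaip3 at -0.71. The Nfkbiz signal of GnRH 3, 4 and 6 (48.6, 69.3 and 70.2) lay below the background controls' mean on such arrays. Steroid hormone receptors and coregulators had a mean of -0.14 (adjusted p = 0.601; Nr3c1 -0.97, Nr3c2 0.76, Ncoa1 -0.57 and -0.19 for its other probe set). The Nr3c1 signal of GnRH 5 was 20.1, and the Nr3c1 difference ran from -1.22 to -0.25 with each array left out. Cytoskeleton and adhesion genes had a mean of 0.17 (adjusted p = 0.337), led by Vasp (1.00), Vcl (0.67) and Actn1 (0.57), where further probe sets gave -0.39 and 0.76 for Vcl and 0.08 for Actn1. Without vehicle 3 these 3 genes differed by 0.30, 0.23 and 0.24. TGF-beta and activin pathway genes had a mean of 0.05 (adjusted p = 0.723), with the activin antagonists Fst at 0.61 and Fstl3 at 0.48 and the activin subunit Inhbb at -1.02. The other tested probe set of Fst gave -0.06. The Inhbb signal of GnRH 3 and 4 (45.7 and 46.8) lay below the background controls' mean on such arrays. The Inhbb difference ran from -3.18 to 0.45 over all alternatives, each set alone included. Housekeeping genes had a mean of 0.21 (adjusted p = 0.337; Gusb 1.01, Pgk1 0.40 and 0.23 for its other probe set, Rplp0 -0.44). Oxidative phosphorylation genes had a mean of 0.15 (adjusted p = 0.337), with Uqcrq at -0.53, Ndufa4 at 0.52 and Ndufb3 at 0.43. Cytosolic ribosomal protein genes had a mean of 0.07 (adjusted p = 0.884; Rps23 0.70, Rpl27 0.42, Rpl11 -0.36), and under quantile normalization the list was called lower at the preset correlation (adjusted p = 0.0272). With an estimated correlation its adjusted p was 0.964 under the main settings, and that correlation was not tried under quantile normalization.

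The study called a gene up when it reached 1.50-fold with at least 50% concordant comparisons. Under that rule 9 of the 32 immediate early transcription factors were up and 0 were down. They were Fosb, Nr4a3, Nr4a1, Egr1 and Egr2 of the genes named above, together with Nfil3, Klf6, Egr4 and Klf2, which were named after their values were seen. Their share of 28.1% compared with 5.79% of all genes (odds ratio 6.45; Fisher's exact test adjusted p = 0.00145 over 25 lists). That test treats genes as independent, and the list's adjusted p was 0.136 by limma's camera with an estimated correlation and 0.116 by exact permutation of its mean. Arc, Ifrd1, Errfi1, Lhb and Cga also met the rule, Rap1b and Fos did not, and Plk2 and Pomc met its mirror image. Of the 18625 tested probe sets, 1419 counted as up and 1415 as down, and without the filter on dim probe sets 3371 and 2826. In data simulated with no change and equal noise on all arrays, the rule counted 1729 to 1806 up.

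Whether the GnRH response differed between preparations was tested as an interaction of agent and set. The 6 genes with the smallest p were Paox, Mrps14, Snapc1, Terf2, Etfrf1 and Rin2. Paox, a polyamine oxidase gene, differed by 3.69 in set II and -0.34 in set III, and the shelterin gene Terf2 by -4.69 and 1.33. The set II means over both agents were 8.48 and 7.79 (log2). The vehicle samples of Paox there lay on average near the background controls' mean, and the GnRH samples of Terf2 below it. The sizes of these differences are therefore uncertain. None of the 6 genes passed (limma adjusted p = 0.669 for each), and over all probe sets 0 passed, with 999 at an unadjusted p under 0.05. Without vehicle 4, which leaves vehicle 3 as the lone vehicle sample of set II, 815 passed. Across probe sets, which are not independent replicates, the set differences correlated weakly, with Pearson r of 0.07 for sets I and II, -0.02 for I and III and -0.09 for II and III.

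More probe sets differed between the enrichment sets than between the agents, but the sets also differed in spike-in level. Vehicle 5, the array of set III with low spike-in signal, resembled set I more than its own set. Its Spearman correlations were 0.875 to 0.884 with the arrays of set I and 0.622 to 0.694 with its set mates. Hsp90ab1, a cytosolic chaperone gene, averaged 12.64 ± 0.20 in set I, 9.25 ± 0.72 in set II and 9.14 ± 0.59 in set III (log2 signal, SD, n = 4 per set). Wapl, a cohesin release factor gene, averaged 10.92 ± 0.26, 5.38 ± 0.25 and 8.58 ± 0.77. Its set II value, pseudocount included, lies below the background controls' mean of 6.47, which is without the pseudocount. The respiratory chain gene Ndufb3, Wdfy1, Ociad2 and the splicing factor gene Srrm2 were likewise higher in set I than in sets II and III. In total 1122 probe sets differed between sets (limma F test adjusted p under 0.05; 5176 at an unadjusted p under 0.05). The count was 127 without vehicle 1, 375 without vehicle 2, 137 without GnRH 1, 175 without GnRH 2, 664 without vehicle 6 and 2332 without vehicle 5, and 628 with quantile normalization. Between sets I and II, 929 were higher and 1409 lower in set II, and between sets I and III, 105 were higher and 250 lower in set III. Sets II and III differed at 1. The sets also differed in spike-in level, and with that level as a covariate, added after the data were seen, 26 probe sets passed the threshold. No gene list, the cell type markers included, differed between set II or III and set I after adjustment by limma's camera (lowest adjusted p = 0.248 and 0.317).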

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

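The tests on background controls, on shared spike-in levels within a set and on the ratio of hormone signals to the brightest spike-in were chosen after the results they weigh were seen.

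A sample was taken as far from its group when its gap to the nearest other array, divided by the range of the 6 arrays of its agent, passed Dixon's 95% limit. This held for 25 of 226 groups of values, where chance gives about 1 in 20, or 11. Vehicle 3 held 14 of the 25. Its median Spearman correlation with the other arrays was 0.34, against 0.62 to 0.69 (gap over range 0.808). Among the rest, its log2 signal was below that of the other vehicle arrays for Calm2 (gap over range 0.864), Vcl (0.825), Hmox1 (0.779), Fst (0.701), Fstl3 (0.682), Vasp (0.664) and Rgs4 (0.663). The same array was lowest in the mean of the TGF-beta and activin pathway genes (0.834), secretory granule genes (0.746), unfolded protein response genes (0.727), heat shock genes (0.7104) and housekeeping genes (0.688).

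The other 11 were spread over 6 arrays. In GnRH 5 the log2 signal was low for Nr3c1 (5.17 against 9.05 to 10.31, gap over range 0.755), Scg2 (0.711) and Dusp1 (0.632), and high for Creld2 (0.783) and Rplp0 (0.683). GnRH 4 was low for the mean of the endothelial markers (0.720) and for Rxrg (0.627). GnRH 3 was low for Trhr (0.650), and GnRH 6 was high for Tshb (14.55 against 13.15 to 13.57, gap over range 0.702). Vehicle 4 was low for Kdr (0.683), and vehicle 6 was high for Ndufa4 (0.677).

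The first pattern weighed was the high scaled spike-in signal on 7 of the 12 arrays. Less labelled sample on those arrays may account for it, since bacterial controls at background were also higher there, by 2.29 on the log2 scale (exact permutation p = 0.00126, two-sided, 7 against 5 arrays). A difference between the 3 preparations stays open, since the sets differ in this level and the array that breaks the pattern is a single one, vehicle 5, at -5.52 from the mean of its 3 set mates (SD 0.84). No biological explanation was tested for it.

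The second pattern was the brighter hormone signals on these 7 arrays, from 2.87-fold for Prl to 11.9-fold for Gh1. A detector ceiling multiplied by the array's scale factor predicts that hormones keep their ratio to the brightest spike-in. For Gh1, Prl, Cga and Lhb together the log2 ratio differed by -1.17 (exact permutation p = 0.00631), which argues against all 4 being at the ceiling on every array. A ceiling reached only on the other 5 arrays would also lower the ratio on the 7, so it stays open. In vehicle 5 these 4 signals were 16159, 18279, 17041 and 12563, against 16641 for the brightest spike-in. For Gh1 alone the log2 ratio differed by -0.14 (exact permutation p = 0.628), so that a ceiling may account for Gh1. More somatotropes and lactotropes in those samples would raise the other markers of these cells. The 8 other markers differed by 0.16 ± 0.38 on average (log2, SE over markers). That mean covers markers from -1.31 for Drd2 to 2.24 for Sstr5. Ghrhr and Ghsr were also higher (0.73 and 0.71), and Pou1f1 and Rxrg lower (-0.67 and -0.38), so this explanation stays open.

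The last pattern was the rise of the immediate early transcription factors after GnRH. A difference in spike-in level between the agents was argued against as the cause. With that level as a covariate, the unadjusted p by limma's camera at the preset correlation was 0.000348 and the mean difference 0.48. Other aspects of array quality were not tested. Under this covariate the secretory and heat shock lists were also called (limma's camera adjusted p = 0.0222 and 0.0482). A shift of all genes at that brightness was argued against as well, since the list's mean of 0.43 stood at percentile 100 of signal-matched random lists, of which 95% lay between -0.08 and 0.20. A response to GnRH is a candidate explanation, as a hypothesis found and tested on the same data.

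Whether chance could give such results was examined by dividing the 12 samples in 100 ways, the real one included. For the count of probe sets changed, 3 divisions gave at least the real 1, and data simulated with no change and equal noise also gave 1, so chance was not taken as excluded for this count. The highest other count was 53, many times the real one. It came from 1 division, and its cause was not tested. Among 100 divisions within the enrichment sets, only the real one gave 1, and the highest other gave 0. For the gene lists at the preset correlation 1 division, the real one, gave 4, and the highest other gave 3. Of the divisions within sets, 1 other also gave 4, and with an estimated correlation or by fry the real count was 0. The lists also share members, so chance was not taken as excluded for this count. For the immediate early transcription factors 1 division gave a p as small as the real 2.41e-05, and the smallest other was 0.000185, or 0.000442 within sets. This unadjusted p at the preset correlation was the smallest of all lists tested, and the other divisions were compared on this list alone. The comparison does not allow for that selection, so chance was not taken as excluded for this p. The list's adjusted p was 0.136 by limma's camera with an estimated correlation and 0.116 by the exact permutation of its mean. For the fold rule the larger of the counts up and down was taken in each other division, since mirrored divisions swap them. By that count 95 divisions reached the real 1419, the highest other being 3515, so chance could not be excluded. For the response that depends on the set the real count by limma was 0 (999 at an unadjusted p under 0.05), which 100 of 100 divisions within sets must reach whatever the data, the highest other also being 0, so this comparison says nothing about chance. For the difference between sets 2 divisions gave at least the real 1122, the real one included. The real sets also differ in spike-in level, so this comparison does not separate the preparations from that level. Chance was not taken as excluded. The highest other count, 1316, came from a division holding 59.9% of the spike-in variance, against 51.7% for the real sets. Divisions holding 71.0%, 71.6% and 76.9% gave 779, 269 and 682, and one holding 54.7% gave 0.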

How the results depend on the processing

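The alternatives on the 5 arrays with the lowest spike-in signal, with the spike-in level as a covariate, and without shared cAMP genes were chosen after the data were seen. The 5 arrays are set I and vehicle 5 of set III, compared without a set term. Where no cause is given, the cause was not tested.

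Of 2761 values for 84 named genes under the alternatives, 2735 kept their direction and side of the threshold or were uncalled in both, 25 lost a call, 1 gained one and 0 reversed a call. The uncalled values included 93 changes of sign. Of 851 list values, 812 stayed, 26 lost a call, 12 gained one and 1 reversed. The log2 difference of Fosb stayed between 1.57 and 3.01 over all alternatives, with limma adjusted p from 0.000168 to 1.00.

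The count of probe sets changed by GnRH, 1, became 0 with pseudocount 1, a filter at the 60th percentile, quantile normalization, no enrichment set term, the set as a random block, no variance trend, each set alone, each set left out, or the 5 arrays with the lowest spike-in signal. With the replicate block, which pairs samples by number, it was 0 as well. With array weights it was 2, where Arc joined Fosb in passing (Arc log2 2.43, adjusted p = 0.0112). With each array left out it ran from 0 to 1, and it was 1 only without vehicle 3.

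The number of lists called, 4, fell to 0 in set II alone, in set III alone, with an estimated correlation and by fry, and to 2 on the 5 arrays. It ran from 3 to 7 with each array left out, with 7 without vehicle 6. The immediate early transcription factors had adjusted p of 0.142 in set II alone, 0.135 in set III alone, 0.136 with an estimated correlation and 0.0650 by fry. For the MAPK feedback regulators these were 0.0991, 0.426, 0.268 and 0.193, and for the cAMP targets 0.0991, 0.505, 0.268 and 0.145. The cAMP targets had 0.351 on the 5 arrays and 0.785 without shared genes. The other immediate early genes had 0.177 in set II alone, 0.957 in set III alone, 0.429 with an estimated correlation, 0.215 by fry, 0.348 with a filter at the 60th percentile, 0.218 without set I, 0.134 without set II and 0.0571 on the 5 arrays. With each array left out they ran from 0.00749 to 0.111.

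The exact p of the mean of the other immediate early genes, 0.0278, became 0.204 with the median and 0.0648 with quantile normalization, and ran from 0.00926 to 0.120 with each array left out. That of the MAPK feedback regulators ran from 0.00926 to 0.0833. The cytosolic ribosomal protein genes changed from a higher to a lower mean under quantile normalization (adjusted p = 0.0272). At the preset correlation, lists that gained a call included the Rap and Ras list with array weights (0.0315), the heat shock and secretory lists without set III (0.0117 each), and the cytoskeleton list without vehicle 6 (0.0247) or GnRH 6 (0.0216).

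The fold rule counted 277 up and 319 down at a fold of 2, 3371 up and 2826 down without a filter, where more probe sets were tested, 924 down with pseudocount 64, and 928 up on the 5 arrays. The interaction count, 0 by limma (999 at an unadjusted p under 0.05), ran from 0 to 815 with each array left out, 815 being without vehicle 4. The lone vehicle sample of a set is then assumed to vary like the others. The count for the difference between sets, 1122, became 628 with quantile normalization and 26 with the spike-in covariate, and ran from 127 to 2332 with each array left out. It was 127 without vehicle 1, 375 without vehicle 2, 137 without GnRH 1, 175 without GnRH 2, 664 without vehicle 6 and 2332 without vehicle 5. The list test was not run with robust moderation or with the set as a random block. Arrays with high scaled spike-in signal stood nearer to background, which limits what dim genes can show.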
